A study of Homo sapiens with 7 samples.

How the data were processed

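Gene expression was measured on 1-colour Affymetrix whole-transcript arrays in MDA-MB-231LN, a derivative of the human breast cancer line MDA-MB-231 that the labels class as claudin-low. Stable sublines carried a doxycycline-inducible hairpin RNA. There were 3 arrays of a non-targeting control hairpin (control shRNA), 2 of the hairpin shKAP1-3 and 2 of the hairpin shKAP1-4, both directed at KAP1, whose gene symbol is TRIM28. Hairpin expression was induced in every culture with doxycycline at 0.5 ug/ml over 7 days, and 250 ng of total RNA went into each labelling. The series design calls the samples biological replicates. The labels name no second subline of a hairpin, no slide and no scan date.

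The deposited values are 1 intensity per probe set and array on a linear scale. The submitters' processing notes name Affymetrix Expression Console and RMA without versions, and the array type and the genome build are not given in the sources used here. The linear scale follows from the values themselves, which on control shRNA replicate 1 reach from 2.60 to 26761. The design had assumed log2 values, so the log2 of each deposited intensity was taken with a pseudocount of 0 before any test. Of the intensities over 50, 53.52% lay within 0.02 of a step on 1 lattice of steps of 1/7, and the sources describe neither how this spacing arose nor whether the values were centred further. The direction of the values is known, since a larger intensity is a brighter probe set.

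The median intensity over all probe sets was 160.9, 172.4 and 165.5 on control shRNA replicates 1, 2 and 3. It was 175.1 and 175.2 on shKAP1-3 replicates 1 and 2, and 151.5 and 156.8 on shKAP1-4 replicates 1 and 2. Over named genes the medians lay between 310.8 and 318.1. The number of arrays limits the precision of every comparison. As a guide to signal near background, 237 olfactory receptor genes had a 95th percentile of 7.15 on the log2 scale, and 4355 of the genes tested (28.55%) lay below it.

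The series matrix held 42934 probe sets. The probe annotation listed 16788 of them, of which 15406 had 1 gene symbol and 1382 had several, and 26146 had no entry and stay unnamed. Probe sets with several symbols were left out of the gene tests. For a gene with several probe sets, the one with the highest mean signal was kept, which gave 15254 genes. RefSeq gene names of the assembly GRCh38.p14 served for checking names, for gene length and for counting neighbouring genes within 500 kb. This updated 0 symbols, and 61 symbols were not found. No coordinates are printed, and GC content was not tested.

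Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values), with 1 coefficient per group and all 7 arrays in 1 fit. The tables were read with data.table (1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The 4 contrasts tested were the mean of both KAP1 hairpins minus control, shKAP1-3 minus control, shKAP1-4 minus control, and shKAP1-4 minus shKAP1-3. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with the standard error (SE) of the fit. On simulated data with the 15254 real genes, the mean contrast recovered 40.3% of genes whose mean changed by 0.25 log2, 79.1% at 0.5, 93.2% at 1 and 93.9% at 2, and called 19 of 14854 unchanged genes. All genes at 0.25 and part of those at 0.5 and 1 had been changed with shKAP1-3 only. A call in the mean contrast therefore does not require a change with both hairpins. For the difference between hairpins the recovery was 67.2% at 0.5, 85.1% at 1 and 97.0% at 2, with 10 of 15054 unchanged genes called.

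The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The naming rule took TRIM28. It then took the 12 highest and 12 lowest fold changes of the mean contrast among called genes whose 4 knockdown arrays all lay on 1 side of the 3 controls. From each gene list it took up to 4 members with the smallest p, and for the hairpin difference the 6 highest and 6 lowest called genes whose arrays did not overlap. SETDB1, CBX5, CDKN1A, MKI67, VIM and CDH1 were named whatever their values. Any other gene named below was chosen after its values were seen.

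The 31 gene lists covered KAP1 and heterochromatin partners, KRAB zinc finger genes of chromosome 19, all ZNF-named zinc finger genes, imprinted genes, clustered protocadherins, cancer-testis genes of the X chromosome and germline genes outside it. They also covered interferon-stimulated genes, S phase genes, G2 and M phase genes, p53 targets, mesenchymal and epithelial genes, breast cancer metastasis genes, NF-kB targets and TGF-beta targets. Further lists held cholesterol synthesis, ATF4 and unfolded protein response, hypoxia, immediate early, autophagy and lysosome, and neuronal genes. Luminal breast, fibroblast, leukocyte and endothelial markers, ribosomal protein genes, replication-dependent histones and olfactory receptors completed the lists tested. The lists of small nucleolar RNAs and of mitochondrially encoded genes had 0 members under their name patterns, below the minimum of 5, so 29 were tested. Each list was tested with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry, which asks whether the genes of a list move on balance in 1 direction. The estimated form also rests its p on the small number of arrays, so p can rise without correlation. In the mean contrast the camera p of TGF-beta targets rose from 0.030 to 0.075, although their estimated correlation was −0.0023. A call lost in that form does not by itself show that correlation between members made it. List tests of each hairpin and of the hairpin difference were added to the planned test of the mean contrast.

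The fold changes of the hairpins against control share the 3 control arrays. Their overlap and correlation are therefore given beside 100 simulations of unchanged groups against the same controls, and beside the overlap of independent lists. Alternatives were quantile normalization and median centring of the arrays, a trended robust eBayes, filters on dim genes, averaging of probe sets, array weights, the replicate number as a block, fits of fewer arrays, the knockdown arrays as 1 group, stricter thresholds, all probe sets, and leaving out each array. Cyclic loess, removal of each array's trends with signal, gene length and neighbouring genes, removal of the length trend alone, and 16 added to each intensity were chosen after seeing the data. Quantile normalization and median centring were set on all probe sets, named or not. Cyclic loess and the trend removals used the named genes only.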

Results

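The series asked which genes KAP1 regulates in MDA-MB-231LN breast cancer cells. KAP1, encoded by TRIM28, is a corepressor that KRAB zinc finger proteins bring to DNA. The data are 7 expression arrays of 15254 named genes, from cells with a control hairpin (n = 3) or 1 of a pair of hairpins against KAP1 (n = 2 each).

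TRIM28 itself fell with both hairpins. Its intensity was 4741 ± 403 (SD, n = 3) in control cells, 710 ± 154 (SD, n = 2) with shKAP1-3 and 886 ± 45.8 (SD, n = 2) with shKAP1-4. The hairpins left 15.0% and 18.7% of the control mean. Single arrays read 4994, 4276 and 4953 in control replicates 1 to 3, 601 and 819 with shKAP1-3, and 854 and 919 with shKAP1-4. The log2 change was −2.75 (SE 0.14, adjusted p = 0.0015) with shKAP1-3 and −2.42 (SE 0.14, adjusted p = 0.0043) with shKAP1-4 in limma. The mean of both hairpins was −2.58 (SE 0.12, adjusted p = 0.0092). The hairpins differed from each other by 0.34 (SE 0.16), which did not pass the test (adjusted p = 0.16). The adjusted p of the mean rose to 0.0996 without control replicate 2, 0.080 without control replicate 3, 0.075 without shKAP1-4 replicate 1 and 0.079 without shKAP1-4 replicate 2. The log2 change itself stayed between −2.70 and −2.47 when any 1 array was left out.

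**Figure D1:**
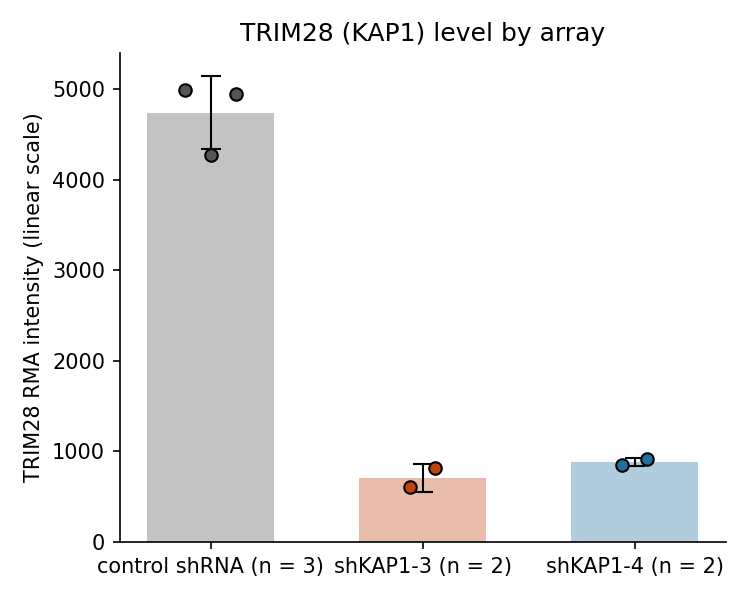
TRIM28 intensity (linear scale, from 0) per group; bars are group means, error bars SD and points single arrays. The 4 knockdown arrays lie between 601 and 919, and the 3 control arrays between 4276 and 4994.

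On the first principal component the arrays of the shKAP1-3 and shKAP1-4 cells lay on opposite sides of the control arrays. It held 60% of the variance over genes. Its scores were 0.638 and 0.513 for shKAP1-3 and −0.355 and −0.372 for shKAP1-4, with the controls between −0.193 and −0.0914. On the second component (16.93%) all 4 knockdown arrays lay on 1 side of the controls, with 0.286 and −0.0393 for shKAP1-3, 0.440 and 0.490 for shKAP1-4, and −0.502 to −0.302 for the controls. Correlations across all probe sets, named or not, were 0.9787 to 0.9808 within the controls, 0.9676 within shKAP1-3 and 0.9763 within shKAP1-4, against 0.9484 to 0.9623 between the hairpins. Of the 7 arrays, 5 correlated best with an array of their own group. The exceptions were shKAP1-3 replicate 2 and shKAP1-4 replicate 1, each closest to control replicate 3 (r = 0.968 and 0.979).

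Among genes that rose in the mean of both hairpins, SAMD9L, an interferon-inducible gene of antiviral and growth restraint, showed the highest change. It rose by 1.12 log2 (SE 0.11, adjusted p = 0.025), by 1.14 with shKAP1-3 and 1.11 with shKAP1-4 (n = 2 each). The difference between the hairpins was −0.03 (adjusted p = 0.91). IGF2BP2, an RNA-binding protein that stabilises mRNAs, rose by 0.78 (SE 0.07, adjusted p = 0.025), and the cytoskeletal linker gene EPB41L2 by 0.77 (SE 0.10, adjusted p = 0.031). The growth-factor response gene EGR1 rose by 0.82 (SE 0.07, adjusted p = 0.025), DOK3, an adaptor of receptor signalling, by 0.70 (SE 0.08, adjusted p = 0.030), and the membrane mucin gene PARM1 by 0.68 (SE 0.07, adjusted p = 0.025). In these last 3 genes the rise was larger with shKAP1-4. The remaining named genes of this side were the pseudogene SUZ12P1 (0.88), the non-coding HCG8 (0.81) and LINC00472 (0.74), the bitter taste receptor TAS2R19 (0.79), the cytoskeletal crosslinker MACF1 (0.67) and CHIC2 (0.66). SUZ12P1, HCG8, TAS2R19, LINC00472 and MACF1 differed between the hairpins and were higher with shKAP1-3. Neither these genes nor CHIC2 were called with both hairpins. HCG8 (7.10) and MACF1 (6.56) had a mean signal below the olfactory receptor reference of 7.15, which is called dim below.

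The genes that fell in the mean of both hairpins included ID1, an inhibitor of basic helix-loop-helix transcription factors, by −1.0 (SE 0.11, adjusted p = 0.026). The interferon-induced genes IFIT3, OASL and IFIT2 fell as well, with IFIT3 at −0.99 (SE 0.16, adjusted p = 0.043), OASL at −0.88 (SE 0.12, adjusted p = 0.033) and IFIT2 at −0.70 (SE 0.05, adjusted p = 0.018). The collagenase gene MMP1 changed by −0.69 (SE 0.08, adjusted p = 0.025), the tight junction gene CLDN4 by −0.62 (SE 0.09, adjusted p = 0.037) and ANGPTL4, a secreted regulator of lipoprotein lipase, by −0.60 (SE 0.07, adjusted p = 0.030). CD63, a tetraspanin of endosomes and exosomes, was at −0.64 and GPX4, which reduces lipid peroxides, at −0.56. The chaperone-like UXT was at −0.64 and LLPH at −0.70, the latter with a dim signal of 6.87. The values per hairpin ran from −0.13 (UXT with shKAP1-4) to −1.17 (IFIT3 with shKAP1-3). Their shared negative sign follows from the naming rule, which took only genes with all knockdown arrays on 1 side of the controls. IFIT3, CD63, GPX4, UXT and LLPH were not called with both hairpins. MMP1 fell more with shKAP1-4, whereas IFIT2, CD63, UXT and GPX4 fell more with shKAP1-3.

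**Figure D2:**
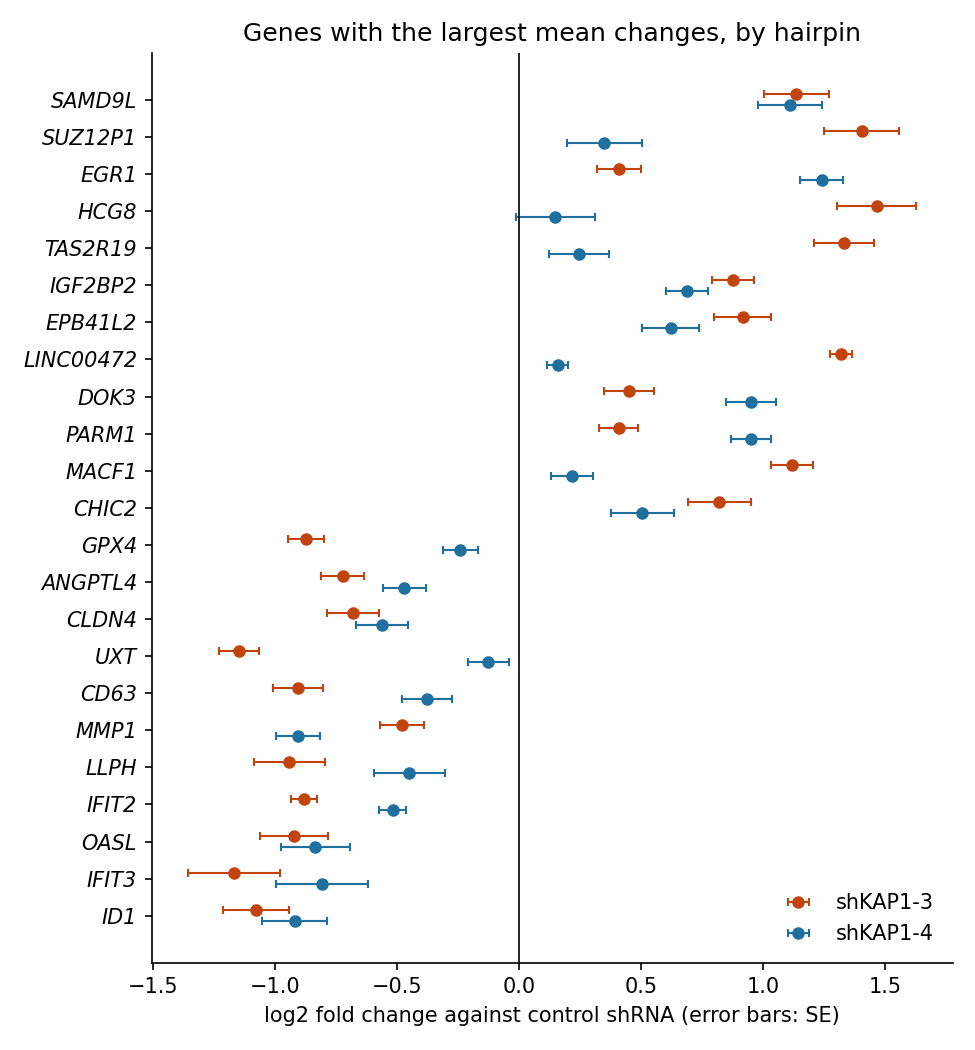
Log2 fold change against control shRNA (horizontal axis) of the 23 named genes other than TRIM28, for each hairpin (n = 2 against n = 3); points are limma estimates and bars their SE. SAMD9L and ID1 have similar values with both hairpins, whereas UXT, HCG8 and LINC00472 moved mainly with shKAP1-3.

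In all, limma called 472 genes in the mean of both hairpins, 227 higher and 245 lower, and 3719 had an unadjusted p under 0.05. At most 46 of the 472 were also called in the same direction with each hairpin, so most lacked such a call. The median size of a called change was 0.33 log2. Only 5 called genes changed by at least 1 log2, namely SAMD9L, TNAP (1.10) and ND6 (1.03) upward and ID1 and TRIM28 downward. TNAP and ND6 fall outside the naming rule, since their knockdown arrays overlapped the controls, and TNAP was dim (3.78). At an adjusted p under 0.01 the calls were TRIM28, LINC00472, the lipid droplet gene PLIN3 (−0.54) and ISCA2 (−0.48), which acts in iron-sulfur cluster assembly. In 196 called genes (90 higher, 106 lower) the 4 knockdown arrays lay on 1 side of all controls. Of all genes tested 1112 (7.29%) were so separated, against 5.71% by chance, a share that does not apply to genes picked by their p. The genes that rose had a median length of 47.83 kb and those that fell 13.54 kb, against 27.22 kb over all genes tested. Scaling shifted the balance of directions. Quantile normalization called 311 higher and 129 lower and cyclic loess 395 and 215, while median centring called 208 and 175. The p values of this contrast measure the spread between arrays of a group, not between the hairpins. With the knockdown arrays as 1 group, which puts the difference between hairpins into the spread, limma called 1 gene. Over all probe sets it called 0 in the mean contrast (7336 at an unadjusted p under 0.05). The count of 472 also rested on single arrays. It was 12, 1 and 0 without control replicates 1, 2 and 3, 249 and 1666 without shKAP1-3 replicates 1 and 2, and 0 without either shKAP1-4 replicate. In the 3 fits with 0 calls by limma, 2648, 3043 and 3110 genes had an unadjusted p under 0.05 (without control replicate 3, shKAP1-4 replicate 1 and shKAP1-4 replicate 2).

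Interferon-stimulated genes went both ways. Of 38 measured, IFIT2, IFIT3, OASL and IFI44 (−0.32) fell and SAMD9L rose (IFI44 with a dim signal of 6.41), and 15 were called when adjusted over the list alone (4 higher, 11 lower). Of 33 breast cancer metastasis genes, MMP1, ID1 and ANGPTL4 fell and the chemokine receptor gene CXCR4 rose (0.25), with 10 called when adjusted over the list alone (2 higher, 8 lower). Among 23 TGF-beta targets, ID1, ID2 (−0.53) and TGFB1 (−0.28) fell, with 7 called when adjusted over the list alone (1 higher, 6 lower). ID2 and TGFB1 fell with shKAP1-3 but lay above control with shKAP1-4, where the list median was −0.016. Of 28 hypoxia genes, ADM (−0.47) and ANGPTL4 fell, with 4 lower when adjusted over the list alone. Of 32 epithelial genes, CLDN4 fell and LSR rose (0.42), with 6 called when adjusted over the list alone (1 higher, 5 lower). Of 25 mesenchymal genes only the collagen gene COL6A1 fell (−0.46), with 4 lower when adjusted over the list alone. CXCR4 and LSR were called higher with shKAP1-4 and not with shKAP1-3.

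Camera called no list as a whole in the mean contrast. It called 0 of 29 (8 at an unadjusted p under 0.05; 0 at either level with an estimated correlation), and fry called 2. Camera called 12 lists without control replicate 1 and 2 without control replicate 2 or without shKAP1-3 replicate 2, 10 under quantile normalization and 4 under median centring or cyclic loess. The smallest adjusted camera p was 0.080, shared by the interferon, epithelial, hypoxia, luminal, fibroblast, histone and ZNF-named lists, against 0.77 with an estimated correlation. It was 0.17 for metastasis genes, 0.11 for TGF-beta targets and 0.26 for mesenchymal genes. The lists called by fry were TGF-beta targets (adjusted p = 0.018, median −0.05) and the 19 imprinted genes (adjusted p = 0.024, median −0.04). Of the imprinted genes 0 were called as single genes by limma, also when adjusted over the list alone (3 at an unadjusted p under 0.05). The hairpins disagreed on TGF-beta targets, for which fry gave adjusted p = 0.94 with shKAP1-4 alone. Fry called that list higher with shKAP1-4 than with shKAP1-3 (adjusted p = 0.0072).

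Other lists held few called genes. Of 354 ZNF-named genes, 10 rose and 2 fell (15 when adjusted over the list alone, 12 higher and 3 lower), while 0 of 65 KRAB zinc finger genes of chromosome 19 were called by limma on either basis (10 at an unadjusted p under 0.05; camera adjusted p = 0.37). The median of the KRAB list was 0.02, its mean −0.0045, and its median turned to −0.01 under quantile normalization. Of the 25 KAP1 and heterochromatin partners, TRIM28 was the only call, also when adjusted over the list alone (camera adjusted p = 0.81). EGR1 and KLF6 (0.21) rose among 20 immediate early genes, whose median was −0.0071 and mean 0.04 (2 when adjusted over the list alone, camera adjusted p = 0.60, upward). ATF4, a stress-induced transcription factor, rose (0.71) among 29 ATF4 and unfolded protein response genes, with a median of −0.03 and a mean of 0.0058 (1 when adjusted over the list alone, camera adjusted p = 0.85, downward). The rise of ATF4 came from shKAP1-3, and the gene was not called higher with shKAP1-4. Single calls were MCM5 (−0.28) of 40 S phase genes, LIF (0.45) of 30 NF-kB targets and H2AC21 (−0.37) of 20 replication-dependent histones, each also the 1 call when adjusted over the list alone. They had camera adjusted p values of 0.19, 0.19 and 0.080. MCM5 was not called lower with shKAP1-4, nor LIF higher with shKAP1-3. IDI1 (0.21) rose of 19 cholesterol synthesis genes (5 when adjusted over the list alone, 3 higher and 2 lower, camera adjusted p = 0.19). It rose with shKAP1-3 and lay slightly below control with shKAP1-4. The protease CTSB fell (−0.37) of 24 autophagy and lysosome genes (3 lower when adjusted over the list alone, camera adjusted p = 0.17). Of 237 olfactory receptors, OR5P2 (0.77), OR5P3 (0.60), OR6A2 (0.40) and OR4K17 (0.36) rose, with 2 when adjusted over the list alone and camera adjusted p = 0.26. All 4 were dim, with a mean signal of 5.03 to 6.37, so the size of their changes is uncertain.

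In the remaining lists limma called 0 genes in the mean contrast. At an unadjusted p under 0.05 there were 4 of 12 protocadherins, 2 of 19 cancer-testis genes, 3 of 26 germline genes, 9 of 44 G2 and M phase genes, 5 of 28 p53 targets, 3 of 29 neuronal genes and 7 of 31 ribosomal protein genes. Among markers of other cell types there were 7 of 22 luminal, 7 of 19 fibroblast, 1 of 18 leukocyte and 4 of 17 endothelial markers. Adjusted over the list alone, 2 luminal markers were lower and the other counts stayed at 0. Camera adjusted p was 0.17 for the protocadherin, cancer-testis, G2 and M phase and neuronal lists, 0.72 for germline genes, 0.57 for p53 targets, 0.29 for ribosomal proteins, 0.26 for leukocyte and 0.89 for endothelial markers. For the germline list the median was −0.0084, the mean 0.02 and the camera direction upward.

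KAP1 partners and markers of growth and cell state that were named in advance did not pass the test in the mean contrast. SETDB1, the histone methyltransferase that acts with KAP1, was at 0.14 (SE 0.06, adjusted p = 0.23) and CBX5, a heterochromatin protein, at 0.05 (SE 0.05, adjusted p = 0.56). The cell cycle inhibitor CDKN1A was at −0.15 (SE 0.07, adjusted p = 0.27) and the proliferation marker MKI67 at 0.12 (SE 0.09, adjusted p = 0.43). The intermediate filament gene VIM was at −0.15 (SE 0.09, adjusted p = 0.36) and the cadherin gene CDH1, with a dim signal of 6.82, at −0.22 (SE 0.08, adjusted p = 0.17). SETDB1 was the exception between hairpins, 0.37 higher with shKAP1-4 (adjusted p = 0.0195).

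With shKAP1-3 alone, limma called 3521 genes against control, 1459 higher and 2062 lower. They included a rise of ATF4 (1.45) and falls of the TGF-beta pathway genes ID2 (−1.23) and TGFB1 (−0.78), the matrix gene SPARC (−1.01) and the replication genes MCM5 (−0.59) and TK1 (−0.68). SPARC and TK1 were chosen after their values were seen. At least 1 log2 separated 112 genes from control (80 higher, 32 lower). The count was 2104 without control replicate 2 and 2046 without control replicate 3. Median centring called 947 higher and 3084 lower, quantile normalization 1170 and 2568, and cyclic loess 1758 and 1484. Over all probe sets, named or not, the balance turned, with 2208 higher and 1405 lower.

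With shKAP1-4 alone, 1005 genes were called, 744 higher and 261 lower. EGR1 (1.24), SAMD9L, LSR (0.86), LIF (0.79) and CXCR4 (0.44) rose, whereas MMP1 (−0.91) and ID1 (−0.92) fell. Of 12 genes that changed by at least 1 log2, 10 rose, among them the antigen presentation genes CD74 (1.37) and HLA-DRA (1.21), and the cystine transporter gene SLC7A11 (−1.01) and TRIM28 fell. CD74, HLA-DRA and SLC7A11 were chosen after their values were seen. The count was 430, 311 and 211 without control replicates 1, 2 and 3, and 372 and 265 without shKAP1-4 replicates 1 and 2. Quantile normalization called 1872 higher and 101 lower and median centring 1638 and 99. Over all probe sets 122 were higher and 204 lower, so the balance turned here too.

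Few genes changed in the same direction with both hairpins. There were 46, of which 19 rose and 27 fell. Upward, beside the genes above, they included the growth factor gene FGF1 (0.33 with shKAP1-3 and 0.98 with shKAP1-4), the small GTPase gene ARL15 (0.73 and 0.38) and the phospholipid flippase gene ATP8B1 (0.61 and 0.49). Downward they included PLIN3 (−0.69 and −0.39), TAX1BP3 (−0.62 and −0.49), the syndecan gene SDC4 (−0.16 and −0.66) and CDKN1B (−0.23 and −0.34), an inhibitor of cyclin-dependent kinases. These examples were chosen after their values were seen. Independent lists of the same sizes would share 71.2 genes upward and 35.3 downward, and 100 simulations of unchanged groups against the same controls gave a mean of 0.01 and at most 1. Almost no gene passes the adjusted threshold where nothing changed. The simulated counts, here and for opposite directions, therefore do not show what shared controls give at the list sizes observed. A larger set of 406 genes was called in opposite directions. Of these, 356 fell with shKAP1-3 and rose with shKAP1-4, and 50 did the reverse, beside 100.6 and 24.96 for independent lists and 0 in the simulations. Without control replicates 2 and 3 the same-direction count was 14 and 16, and without shKAP1-4 replicates 1 and 2 it was 13 and 10. The opposite count was 154, 114 and 67 without control replicates 1 to 3, and 164 and 126 without the shKAP1-4 replicates. It was 863 under median centring, 789 under quantile normalization, 289 under cyclic loess and 269 after removal of the trends with signal, gene length and gene density, and the same-direction count was 76 under quantile normalization.

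Across genes, which are not independent replicates, the fold changes of the hairpins had a Pearson r of −0.075 and a Spearman rho of −0.096. Unchanged groups sharing the controls gave a mean r of 0.40, from 0.34 to 0.44. The covariance was −0.0040 against 0.0046 in the simulations (0.0037 to 0.0054), a difference of −0.0086. The 3 controls cannot be split into a pair of sets of at least 2 arrays, so part of any overlap may come from sharing them. Without control replicate 1, r was 0.024.

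**Figure D3:**
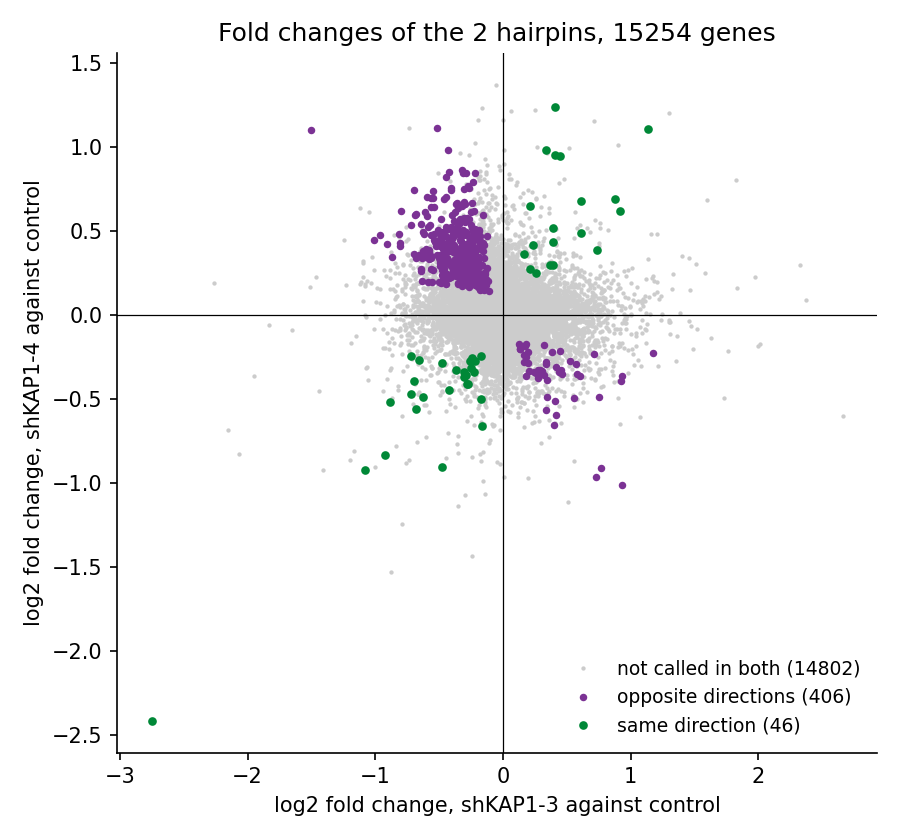
Log2 fold change against control shRNA with shKAP1-3 (horizontal axis) and shKAP1-4 (vertical axis); each point is 1 of 15254 genes, with the 46 genes called in the same direction in green, the 406 called in opposite directions in purple and the others in grey. Most purple points are genes lower with shKAP1-3 and higher with shKAP1-4.

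Compared directly, the hairpins differed in more genes than KAP1 knockdown and control did. VPS37C, a subunit of the endosomal sorting complex, was 2.60 log2 higher with shKAP1-4 than with shKAP1-3 (SE 0.15, adjusted p = 5.1e-04), lower than control with shKAP1-3 (−1.50) and higher with shKAP1-4 (1.10). The ubiquitin-binding UBQLN4 differed by 1.85 (SE 0.24, adjusted p = 0.0034) and the histone genes H2BC3 and H2AC12 by 1.77 (SE 0.36, adjusted p = 0.015) and 1.76 (SE 0.24, adjusted p = 0.0040). LBHD1 differed by 1.70 and COMMD6 by 1.67. On the other side, ND6, a mitochondrially encoded subunit of complex I, was at −3.26 (SE 0.23, adjusted p = 7.3e-04), with 2.66 in shKAP1-3 and −0.60 in shKAP1-4. The nuclear non-coding RNA MALAT1 was at −2.22 (SE 0.12, adjusted p = 4.7e-04), and the taste receptors TAS2R4 and TAS2R20 were at −2.29 and −2.18. SUMO4 (−2.19) and FAM133B (−2.03) completed this side. VPS37C, TAS2R4, TAS2R20, SUMO4 and FAM133B had a mean signal below the olfactory receptor reference.

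In total 4843 genes differed between the hairpins, 2814 higher and 2029 lower with shKAP1-4, and 244 by at least 1 log2. The median of all named genes was −0.03 in this comparison and moved to 0.15 under quantile normalization and 0.16 under median centring. There 5881 and 6346 genes were higher and 973 and 780 lower. Both scalings were set on all probe sets, whose array medians ran from 151.5 to 175.2, against the narrower 310.8 to 318.1 for named genes. Centring on the named genes alone was not run. Cyclic loess, on the named genes, gave 2326 higher and 2242 lower. Over all probe sets, 2406 were higher and 4138 lower, the reverse of the balance among named genes. The count was 3158 and 3008 without shKAP1-4 replicates 1 and 2, which was over 1.5 times lower.

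KRAB zinc finger genes of chromosome 19 lay on opposite sides with the hairpins. With shKAP1-3, 9 of 65 rose (4 when adjusted over the list alone), among them ZNF226 (0.70) and ZNF83 (0.45), and the list median was 0.13 above that of all genes (0.08 under quantile normalization, where the unadjusted median was −0.0035). With shKAP1-4, ZNF180 (−0.38), ZNF160 (−0.33) and ZNF528 (−0.31) fell (2 when adjusted over the list alone), and the median lay at −0.115 relative to all genes under the deposited values. Camera gave adjusted p = 0.0016 upward and 0.0067 downward, but 0.748 and 0.897 with an estimated correlation. Between the hairpins, 16 members were lower with shKAP1-4, also 16 when adjusted over the list alone, with a median of −0.23 relative to all genes (camera adjusted p = 2.2e-05; 0.700 with an estimated correlation). The zinc finger genes named here were chosen after their values were seen, and ZNF226 (5.77), ZNF83 (6.57) and ZNF180 (6.08) had a mean signal below the olfactory receptor reference, so the size of their changes is uncertain.

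Other lists shifted by camera with 1 hairpin. With shKAP1-3, 8 of 40 S phase genes fell and 1 rose (9 when adjusted over the list alone, adjusted p = 0.040; 0.974 with an estimated correlation), with a median of −0.15 relative to all genes that moved to −0.09 under cyclic loess. Likewise 12 of 38 interferon-stimulated genes fell and 2 rose (20 when adjusted over the list alone, adjusted p = 0.040; 0.748 with an estimated correlation). Of 20 histone genes 6 fell (6 when adjusted over the list alone, adjusted p = 0.020; 0.748 with an estimated correlation). All ZNF-named genes moved up on balance, with 59 higher and 26 lower (85 when adjusted over the list alone, adjusted p = 0.020; 0.748 with an estimated correlation), although their median of 0.04 turned negative under quantile normalization and median centring. Olfactory receptors were also called, with 17 of 237 higher (10 when adjusted over the list alone, adjusted p = 0.020; 0.748 with an estimated correlation), and their median of 0.06 likewise turned negative under both and was 0.03 under cyclic loess. Fry called 7 lists with shKAP1-3, among them TGF-beta targets (adjusted p = 0.0028), which camera did not call (adjusted p = 0.080; 0.748 with an estimated correlation).

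With shKAP1-4, hypoxia genes lay lower. ADM (−0.27), the glycolytic genes PGK1 (−0.27), PFKP (−0.27) and PFKFB3 (−0.26), and ANGPTL4 (−0.47) fell among 28, with 10 called when adjusted over the list alone (1 higher, 9 lower). The camera adjusted p was 0.0026, against 0.897 with an estimated correlation, and the list median was −0.13 relative to all genes. Protocadherins were at −0.16 relative to all genes, with PCDHB1, at a dim signal of 5.20, lower (−0.21; 2 when adjusted over the list alone; adjusted p = 0.014, and 0.897 with an estimated correlation). Neuronal genes, with the synaptic vesicle gene SYP lower (−0.46), and X-linked cancer-testis genes, with 0 calls by limma (4 at an unadjusted p under 0.05), had adjusted p = 0.032 each and 0.897 with an estimated correlation. The medians of both, −0.07 and −0.06 relative to all genes, turned positive before that subtraction under quantile normalization and median centring, and under cyclic loess moved to −0.04 and −0.03. Fry called 0 lists with shKAP1-4 and 5 at an unadjusted p under 0.05.

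Between the hairpins, 10 of 40 S phase genes were higher with shKAP1-4, also 10 when adjusted over the list alone, among them MCM5 (0.61), TK1 (0.92) and UNG (0.94). The list median was 0.21 above that of all genes, and 0.08 under cyclic loess (camera adjusted p = 0.031; 0.860 with an estimated correlation). Of 237 olfactory receptors 29 were lower and 1 higher (10 when adjusted over the list alone, camera adjusted p = 0.0101; 0.860 with an estimated correlation), and their median of −0.14 turned positive under quantile normalization and median centring and was −0.065 under cyclic loess. Fry called 8 lists in this comparison.

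**Figure D4:**
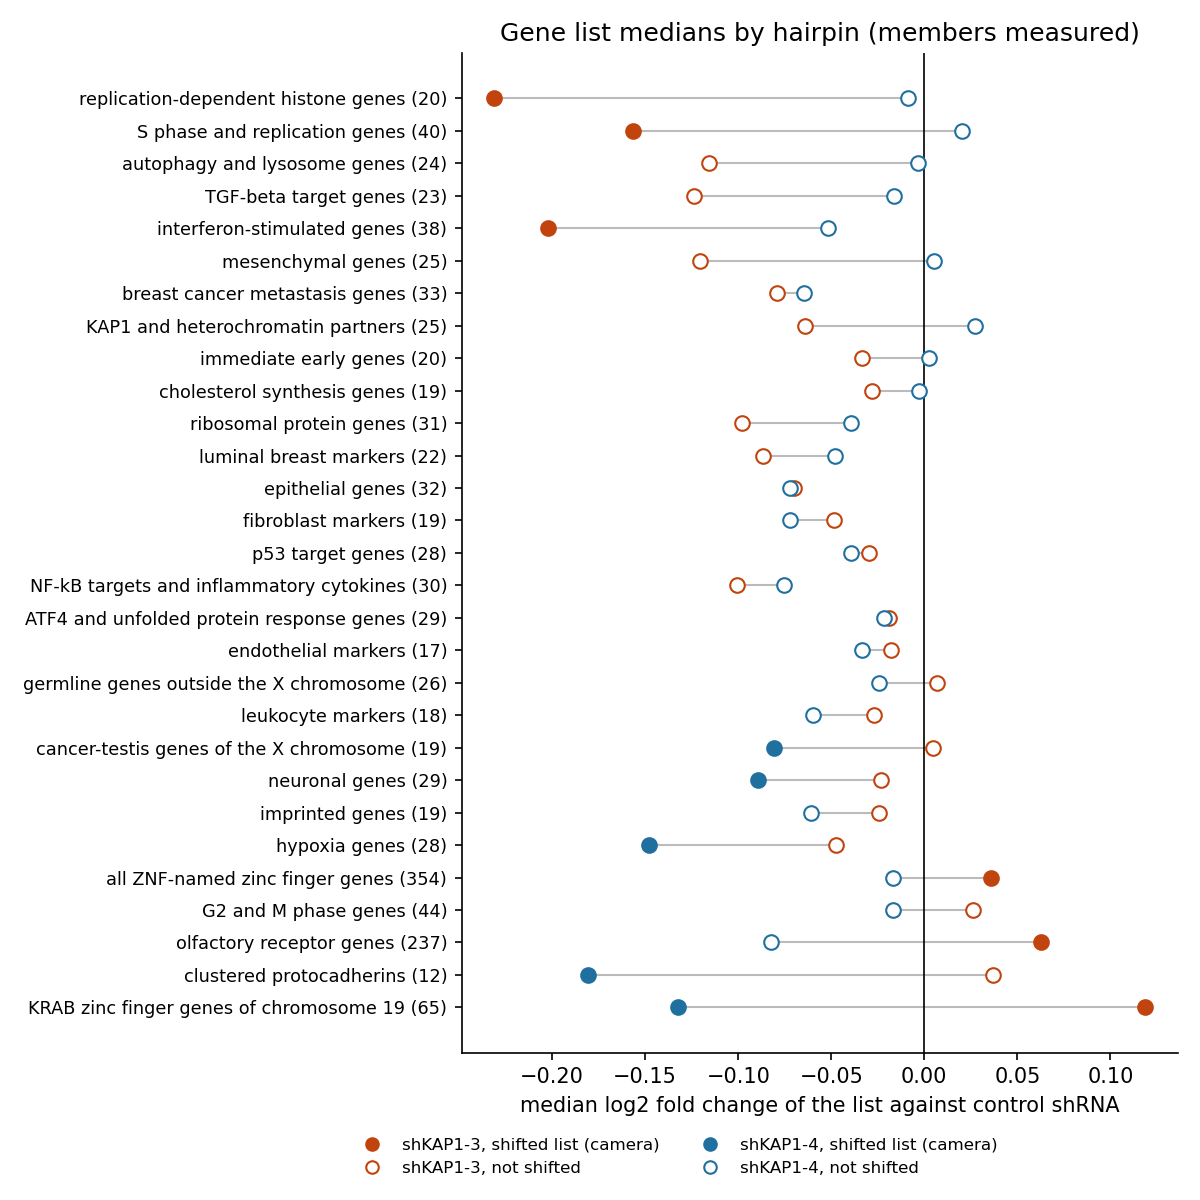
Median log2 fold change against control shRNA (horizontal axis) of each of 29 gene lists, with the number of measured members in brackets, for shKAP1-3 and shKAP1-4; filled points are lists called by camera at the preset correlation. KRAB zinc finger genes lie at opposite sides of 0 (the shKAP1-3 median turns to −0.0035 under quantile normalization), and the positive ZNF-named and olfactory medians of shKAP1-3 and the negative neuronal and cancer-testis medians of shKAP1-4 change sign under quantile normalization and median centring.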

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

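The tests of a weaker knockdown, a mislabelled array and hairpin or subline effects were chosen only after the result was seen.

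The results below stood out because the hairpins, which target the same gene, differed from each other in a direct limma test with an adjusted p under 0.05. In all 4843 genes did so. Among the genes named for the mean of both hairpins, those higher with shKAP1-4 were UXT (difference 1.02 log2), EGR1 (0.83), GPX4 (0.63), PARM1 (0.54), CD63 (0.53), DOK3 (0.50) and IFIT2 (0.36). Those lower with shKAP1-4 were HCG8 (−1.32), LINC00472 (−1.16), TAS2R19 (−1.09), SUZ12P1 (−1.06), MACF1 (−0.90) and MMP1 (−0.43). At the ends of the comparison stood VPS37C (2.60), UBQLN4 (1.85), H2BC3 (1.77), H2AC12 (1.76), LBHD1 (1.70) and COMMD6 (1.67), and in the other direction ND6 (−3.26), TAS2R4 (−2.29), MALAT1 (−2.22), SUMO4 (−2.19), TAS2R20 (−2.18) and FAM133B (−2.03). SUMO4, FAM133B, TAS2R4, TAS2R20, VPS37C, HCG8 and MACF1 were dim. Of the gene lists, the median difference was −0.26 for KRAB zinc finger genes of chromosome 19 and 0.18 for S phase genes (0.08 under cyclic loess), and −0.14 for olfactory receptors, which turned to 0.07 under quantile normalization.

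A signal also appeared in the 26146 probe sets without a gene name, which no comparison of named genes used. Against control, 1514 of them were called higher and 499 lower with shKAP1-3, and 31 higher and 196 lower with shKAP1-4, and 22 were called in the same direction with both hairpins and 33 in opposite directions. In the mean of both hairpins limma called 0 of them, with 4790 at an unadjusted p under 0.05.

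The hairpins differed although TRIM28 fell in both, and of the genes called with both, 46 moved in the same direction and 406 in opposite directions. Mean signal correlated with the fold changes at a Spearman rho of −0.264 with shKAP1-3 and 0.247 with shKAP1-4. After cyclic loess 4568 genes differed, and 5504 after removal of the trends with signal, gene length and gene density. Of these, 3822 and 3585 were among the original 4843, which argues against such trends as the whole cause of the difference. The count in opposite directions fell to 289 and 269 in these settings, so part of the opposition went with the trends. A weaker knockdown by 1 hairpin would give a scaled copy of the other hairpin's changes, but the covariance of the fold changes was −0.004006, below the lowest value simulated from shared controls (0.0037). The simulations held no trend of the arrays, and opposite trends with signal can lower the covariance. The value therefore speaks only against a weaker knockdown as the whole cause, and a shared response beneath the trends is not excluded. A mislabelled array was tested by asking which arrays correlate best with another group, and 2 did, the sign that test had named, yet TRIM28 parted the lowest control from the highest knockdown array by 2.219 log2, and the arrays of a hairpin correlated at 0.9676 or more against at most 0.9623 across hairpins. Effects of the hairpin or subline other than through KAP1 could account for the difference and cannot be told apart from KAP1 effects, because the labels give 1 group of arrays per hairpin. The same holds for a batch of cultures, RNA or arrays that went with a hairpin, since the labels name no slide and no scan date.

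KRAB zinc finger genes of chromosome 19 lay higher with shKAP1-3 and lower with shKAP1-4, relative to all genes. Drift of probe sets of this signal level was tested with 10000 random lists matched on signal, whose medians ran from −0.1875 to −0.0105, and the list median of −0.2555 lay at percentile 0. A trend with signal, gene length and gene density was removed, and the median was still −0.2389 with a camera adjusted p of 0.00012. These values argue against both as the whole cause, but the camera call is lost with an estimated correlation (adjusted p = 0.700). That form called 0 lists in this comparison, so the loss does not separate correlation between members from the small number of arrays. The effect of the hairpin, the subline or a batch stays open here as well, and no biological explanation beyond the hairpin groups was tested.

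Genes that fell in the mean of both hairpins were shorter (median 13.54 kb) than genes that rose (47.83 kb), against 27.22 kb for all genes tested. The length trend as the whole cause of the calls is argued against by 81.36% of the called genes staying called with the same sign after its removal, although the medians then moved to 21.79 and 27.01 kb. A length trend that also varies between arrays of a group cannot be told apart from an effect of knockdown. The largest gap in length slope within a group was 0.05234, close to the 0.0592 between the knockdown and control means. The sources name no property of the RNA that could be tested against it.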

How the results depend on the processing

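The settings chosen only after the result was seen were cyclic loess, removal of array trends, and 16 added before the log2. All 144 named gene and contrast pairs kept 1 sign under every alternative run, but of 56 called pairs 48 lost the call under at least 1. For genes that the naming rule took only if their arrays did not overlap, leaving out 1 array could not turn the sign. List members were taken by their smallest p in these data, which also favours a kept sign. Over single genes and lists, 4369 alternative values kept their side of the threshold, 176 newly passed it and 434 no longer passed. A further 13 values that were called in the main fit reversed in sign. Sign changes of values not called in the main fit were not counted as reversals. Of the answers to the comparisons, 121 stayed, 64 moved, 5 weakened and 1 reversed. The arrays' signal over background limits the dim genes, since 4355 genes lay below the olfactory receptor reference. Where no reason is given, the cause was not tested.

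Leaving out 1 array gave 0 to 1666 genes for the mean of both hairpins, 2046 to 4026 for shKAP1-3, 211 to 1157 for shKAP1-4 and 3008 to 5014 between hairpins. Genes in the same direction with both hairpins ranged from 10 to 53 and in opposite directions from 67 to 569, r from −0.118 to 0.024 (reversed without control replicate 1), lists from 0 to 12, and TRIM28 from −2.70 to −2.47. Of the 1666 genes called without shKAP1-3 replicate 2, 447 were among the original 472. A hairpin left with 1 array is assumed to vary like the other groups. TRIM28 lost its call without control replicate 2 (−2.66), control replicate 3 (−2.55), shKAP1-4 replicate 1 (−2.56) and shKAP1-4 replicate 2 (−2.61), always with a negative change.

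With the replicate number as a block, limma called 0 genes in the mean contrast (2654 at an unadjusted p under 0.05), 1436 with shKAP1-3 and 0 with shKAP1-4 (2592 at an unadjusted p under 0.05), so that 0 genes were shared in the same or in opposite directions. TRIM28 was at −2.55 (adjusted p = 0.172; 0.0014 to 0.172 over its alternatives). By its construction the block leaves control replicate 3, which has no partner, without weight. Arrays of the same number had deviations from their group means correlated at −0.138 to 0.291. Control and shKAP1-4 arrays gave 0.171 and 0.291, control and shKAP1-3 arrays −0.037 and −0.138, and the hairpins −0.128. In a group of 2 arrays the deviations mirror each other, so these values cannot settle whether the numbers pair the samples.

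Quantile normalization gave 1973 genes with shKAP1-4, 76 in the same and 789 in opposite directions, and 10 lists in the mean contrast (1 higher, 9 lower). It turned the medians with shKAP1-3 of KRAB (−0.0035), ZNF-named (−0.038) and olfactory receptor genes (−0.086), with shKAP1-4 of cancer-testis (0.028) and neuronal genes (0.018), and between hairpins of olfactory receptors (0.071). Median centring gave 1737 genes with shKAP1-4, 863 in opposite directions and 4 lists. It turned ZNF-named (−0.040) and olfactory receptor genes (−0.013) with shKAP1-3, cancer-testis (0.028) and neuronal genes (0.019) with shKAP1-4, and olfactory receptors between hairpins (0.045). Both were set on all probe sets, named or not, and shift the median of all named genes. Relative to that median all these list medians kept their sign except the olfactory receptors with shKAP1-3 under quantile normalization (−0.0035). Cyclic loess gave r of −0.027 and 4 lists, all lower. Removing the trends with signal, length and density gave 269 genes in opposite directions, r of −0.028, 3 lists (2 higher, 1 lower), and a cancer-testis median of 0.012 with shKAP1-4.

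Without the dimmest genes 792 were called in the mean contrast under the lighter filter and 916 under the heavier one, which left fewer genes to test, where r was −0.140 and the ZNF-named median with shKAP1-3 was −0.050. Array weights gave 807 genes in the mean contrast and 1906 with shKAP1-4. The knockdown arrays as 1 group gave 1 gene (969 at an unadjusted p under 0.05) and 5 lists, all lower; this puts the difference between hairpins into the spread. Fry called 2 lists. The knockdown arrays alone gave 2606 genes between hairpins, a fit with fewer samples. A log2 change of at least 1 left 5, 112, 12 and 244 genes in the mean, shKAP1-3, shKAP1-4 and hairpin comparisons, and an adjusted p under 0.01 left 4, 1373, 230 and 2422. Over all probe sets, limma called 0 in the mean contrast (7336 at an unadjusted p under 0.05), 3613 with shKAP1-3, 326 with shKAP1-4 and 6544 between the hairpins, the balance of directions having turned in these last 3.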

Other observations

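The tests of the taste receptor family, the removal of array trends and the splits with a mean per hairpin were chosen only after the result was seen.

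Of 19 cholesterol synthesis genes, limma called 4 higher and 3 lower with shKAP1-3 (8 when adjusted over the list alone, 5 higher and 3 lower), and the list as a whole was not called (camera adjusted p = 0.811, 0.974 with an estimated correlation; fry adjusted p = 0.658). STARD4, a sterol carrier, rose by 1.04 log2 and the sterol oxidase gene MSMO1 by 0.95, with SC5D (0.75) and IDI1 (0.50), whereas EBP (−0.74), NSDHL (−0.59) and the mevalonate kinase gene MVK (−0.41) fell. Between the hairpins STARD4 was at −1.23 (adjusted p = 0.0018) and MVK at 0.71 (adjusted p = 0.0012) in limma. The stress response genes ATF4 and SLC7A11 differed likewise, at −1.49 (adjusted p = 4.7e-04) and −1.94 (adjusted p = 0.0016). These genes are named because of their values.

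The genes of this paragraph were also picked singly for their values, and of 22 luminal markers limma called 6 higher with shKAP1-4 than with shKAP1-3 and 0 lower, also 6 when adjusted over the list alone. Fry called this list (adjusted p = 0.046) and camera did not (adjusted p = 0.276; 0.860 with an estimated correlation). The receptor gene ERBB2 was −0.49 with shKAP1-3 and 0.31 with shKAP1-4, a difference of 0.80 (adjusted p = 4.3e-04), and the luminal transcription factor gene GATA3 was −0.33 and 0.32, a difference of 0.64 (adjusted p = 0.0018). The placental retrotransposon-derived gene PEG10 fell with shKAP1-3 (−0.63) and differed by 0.95 (adjusted p = 0.0012). The meiotic gene HORMAD1, at a dim mean signal of 4.75, rose with shKAP1-3 (1.35) and was lower with shKAP1-4 by comparison (−1.62, adjusted p = 0.0012).

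A hypothesis from the data is that bitter taste receptor genes as a family lay higher with shKAP1-3. It arose because TAS2R4, TAS2R20 and TAS2R19 were among the extreme genes. Of 21 measured, 8 were called higher with shKAP1-3 (median 0.68), 2 in the mean of both hairpins (median 0.23) and 0 by limma with shKAP1-4 (median −0.08), and 8 were lower in the difference between hairpins (median −0.70). A trend of the arrays with signal, gene length and gene density could lift such dim genes together, but after its removal the median with shKAP1-3 was still 0.6359. Drift of probe sets of this signal level was tested on the 18 members other than those 3, whose median of 0.45 lay at percentile 100 of 10000 random lists matched on signal (−0.07 to 0.21). Camera passed 0.05 at the preset correlation and no longer did with an estimated one, and 4 members lay at or below 0 with shKAP1-3. Of the 21 genes 19 lie below the olfactory receptor reference, and they are paralogs whose probe sets need not be independent. The subline, or a batch that went with it, stays open as a source.

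Chance could not be excluded for the grouping of arrays into knockdown and control where the 4 knockdown arrays are taken as 1 group. There the real split called 1 gene, and the highest of the other splits also called 1. In all 2 of the 35 splits of the 7 arrays, the real one included, gave as many genes. The other split set shKAP1-3 replicates 1 and 2 with shKAP1-4 replicate 2 against the rest. That fit puts the difference between hairpins into the spread, so it decides little about the 472 genes called with a mean per hairpin. With a mean per hairpin, 2 of 100 drawn of the 105 splits into groups of 3, 2 and 2 gave at least 472 genes, the real one included. Most of them part the arrays of a hairpin and so carry its difference in the spread, and 92 called 0 genes, so this count excludes nothing. Only 7 splits keep the arrays of each hairpin together, too few for a share under 0.05. Of these 2 gave at least 472 genes, the real one with 472 and the highest other with 852, which set control replicate 2 with both shKAP1-4 arrays.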
